A study of Homo sapiens with 2 samples.

How the data were processed

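The series title names the cells as MV4;11. Their RNA was sequenced as 150 bp paired-end libraries, per the labels' protocols. MV4;11 is an established human acute leukaemia line of myelomonocytic type. It carries a KMT2A-AFF1 fusion and an internal tandem duplication (ITD) in the receptor tyrosine kinase gene FLT3. There were 2 libraries. The labels give the genotype of 1 as FLT3-ITD and of the other as FLT3-ITD/D835, and each group therefore held 1 library. D835 is the aspartate at residue 835, in the activation loop of the FLT3 kinase domain. The substituted amino acid and the way in which the D835 cells were obtained are not given in the sources used here. The sample titles add the numbers 5 (FLT3-ITD) and 11 (FLT3-ITD/D835) to the name of the line, and whether these mark clones is not given either.

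The deposited table held whole-number read counts per gene for 28395 genes, with NCBI gene identifiers, exon coordinates and exonic lengths. STAR, featureCounts and the hg38 build are named in the submitters' processing notes. Their versions, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Coordinates are those of the deposited table, on hg38, and give the outermost exon boundaries of each gene. Library columns were matched to samples by the sample descriptions, and no other per-sample column was present. Rows without a gene symbol (475) carried 0.0397% of the FLT3-ITD and 0.0451% of the FLT3-ITD/D835 counts. They were kept under their gene identifier. A gene type was found by gene identifier in a GRCh38.p14 RefSeq table for 27745 of the genes (97.7%).

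A pair of features of the counting bears on the precision. Among genes with 1 to 20 counts, 68.0% of the FLT3-ITD values and 68.1% of the FLT3-ITD/D835 values were even, against 50.7% and 51.0% among genes with over 200 counts. Counting the mates of a pair separately gives such an excess of even numbers, and the counting intervals below are then too narrow, so the gene counts were repeated on halved counts. The near-identical copies SMN1 and SMN2 had close counts. SMN1 had 2857 and 3538 counts in the FLT3-ITD and FLT3-ITD/D835 libraries and SMN2 had 2765 and 3410, so reads shared between copies were not left out, and the values of such genes are uncertain. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart.

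The counts as deposited were scaled with edgeR 4.0.16 (TMM factors 0.997 and 1.003) in R 4.3.3, and normalised counts per 1000000 (CPM) are relative to those effective totals. With 1 library per group there are no residual degrees of freedom, so edgeR's quasi-likelihood test could not be fitted and no p-value is given. Log2 ratios are FLT3-ITD/D835 over FLT3-ITD, with 0.5 counts added to each library. Each ratio has an exact Clopper-Pearson 95% interval conditional on the gene's summed counts (scipy 1.17.1). Intervals and detection limits cover counting error only. They do not cover the spread between cultures, clones or library preparations, which was not measured, and reads are not independent molecules. A gene was called higher or lower where its whole interval lay beyond 2-fold, among genes with at least 1 CPM in at least 1 library. A value of 0 allows up to 3 counts, which was 0.0817 CPM in the FLT3-ITD and 0.0787 CPM in the FLT3-ITD/D835 library, and folds against 0 are lower bounds computed from that limit. The limit is 1-sided, so for genes at 0 the 2-sided interval reaches a smaller fold than the bound given. If mates were counted separately, these bounds are too large by 2-fold.

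There were 37 gene lists (signalling, lineage, cell cycle, metabolism, stress, immunity and markers of other cell types), written before the data were examined, as were the calling rule, the rule for named genes and the alternatives. All listed genes except GSTT1 were matched in the table. For each list with at least 8 measured genes the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described as standing apart below the 2.5th or above the 97.5th percentile. Placing genes at 0 in a library at their 3-count limit left every list median as it was. Percentiles describe this pair of libraries and are not p-values, because genes of a pathway vary together. Autosomes and X were treated in the same way with protein-coding genes only.

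The named genes were FLT3, and the 15 highest and 15 lowest protein-coding genes with at least 5 CPM in at least 1 library, ranked by the interval bound nearest to no difference. Up to 4 members of each list with at least 5 CPM were added, first those called, otherwise the 2 with the highest mean level. A gene outside that rule is introduced as chosen after its values were seen.

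The calling and list steps were tested on simulated data. Poisson counts were drawn for the real genes at their mean over both libraries and the real totals, with 200 genes changed. The draw held no spread between libraries beyond counting and no separately counted mates. It therefore checks the calculation and does not give the rate of false calls in the real libraries. In all, 12563 genes entered the step, and none of the 12363 unchanged genes was called. Of genes raised 3-fold 26 of 26 were called, and of those lowered 3-fold 21 of 24. None of the 50 genes changed 1.5-fold was called, and 95.0% of intervals held the simulated ratio. A shift of 0.5 added to the DNA replication list among reshuffled ratios of 12843 genes put it at the 100th percentile, and 2 of the other 35 lists stood apart.

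The alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, other filters, 5 added counts, removal of length and GC trends (GC content from GENCODE release 29 transcripts), other fold thresholds, thinning of the deeper library, mean in place of median and length-matched random lists. A transcript start was called CpG-rich where the first 300 bases of the longest GENCODE transcript had at least 55% GC and an observed over expected CpG ratio of at least 0.6, a proxy for the promoter. Chromosome arms, runs of 20 neighbouring genes, genes found in only 1 library, halved counts, and the repeats without mitochondrial genes or without the short arms of chromosomes 10 and 20 were chosen after the data were seen. The FLT3 genotype of the cells is not analysed here, and the values of some genes and a test that needs them are not reported here.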

Results

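Gene expression was measured by RNA sequencing in MV4;11 leukaemia cells with FLT3-ITD alone and in MV4;11 cells labelled FLT3-ITD/D835, with 1 library each. The table held 36825911 counts for the FLT3-ITD library and 37995488 for the FLT3-ITD/D835 library. At least 1 CPM was reached by 12514 and 12112 genes, respectively. Neither genotype was replicated, so every difference below is between these 2 libraries, and the intervals are exact 95% counting intervals of the log2 ratio.

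The study asked how cells with and without the D835 mutation differ in expression. FLT3 itself (chromosome 13, 28003274 to 28100592, minus strand, hg38) was abundant in both libraries, with 14556 counts in FLT3-ITD cells and 13005 in FLT3-ITD/D835 cells. These counts corresponded to 397 and 341 CPM, a log2 ratio of -0.22 (-0.25 to -0.18). Gene counts do not show which FLT3 allele a read came from, so this value does not check the genotype labels. The list of FLT3, cytokine receptor, STAT5 and STAT5 target genes did not stand apart from random lists. None of its 22 measured genes had a whole interval beyond 2-fold, 12 had a ratio above 1, and the median log2 ratio was 0.10 (76.2nd percentile of random lists). SPI1, which encodes the myeloid transcription factor PU.1, was at 179 and 269 CPM, a log2 ratio of 0.59 (0.54 to 0.63). Output genes of the RAS-ERK pathway had a median of 0.08 (77.0th percentile), with 2 of 15 genes higher and 1 lower, although by the mean the list stood above random lists (97.6th percentile). DUSP4, a MAP kinase phosphatase, was higher with D835, at 2.64 and 21.7 CPM (log2 ratio 3.03, 2.73 to 3.35).

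The libraries differed at many genes. Of 12843 expressed genes, 459 were higher and 1016 lower with D835 by more than 2-fold over the whole interval, together 11.5% of the genes. Lower genes made up 68.9% of those called. Across 12123 genes with at least 100 summed counts the robust SD of the log2 ratio was 0.52, against a median half-width of the counting interval of 0.12, and 14.2% of these genes had a point estimate beyond 2-fold. From here on, genes of a list described as higher, lower or beyond 2-fold had their whole interval beyond 2-fold. Without replicates the part of this spread that goes with the genotype is not known.

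**Figure D1:**
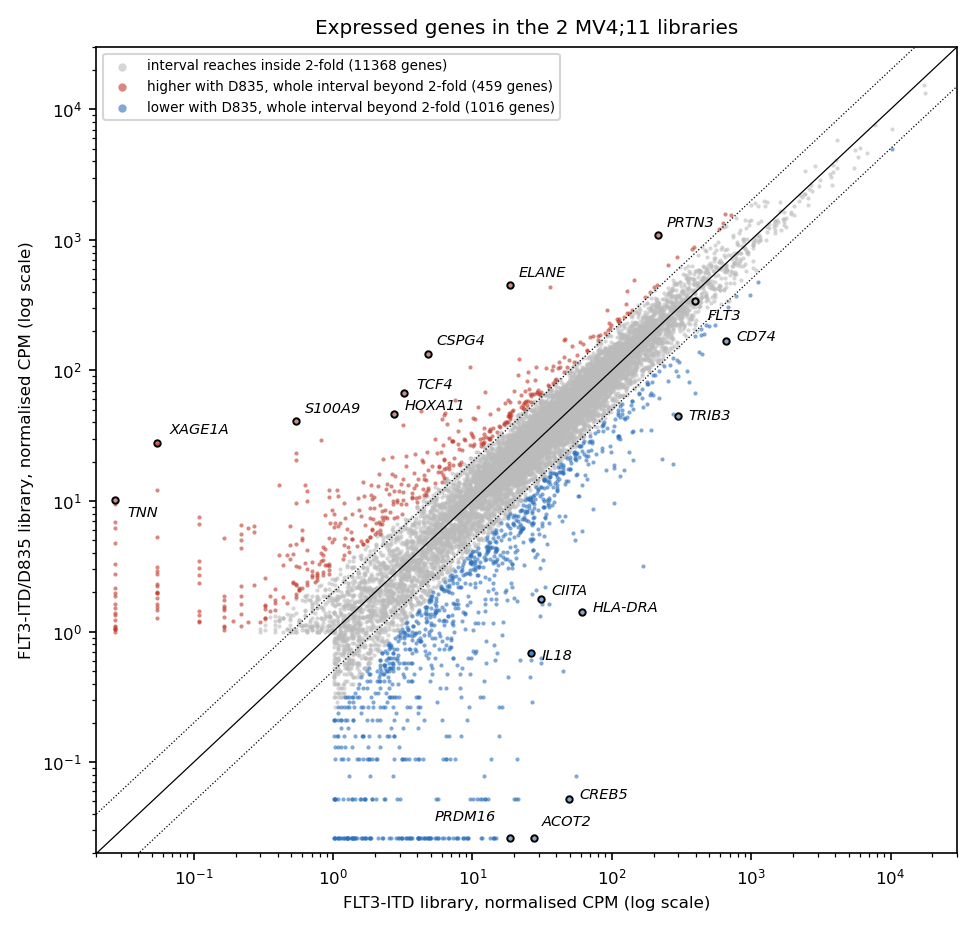
Normalised CPM of each expressed gene in the FLT3-ITD library (x axis, log scale) and the FLT3-ITD/D835 library (y axis, log scale), 1 library per genotype, with genes at 0 drawn at the level of 1 count. The solid line marks equal levels and the dotted lines 2-fold differences; 459 genes were higher (red) and 1016 lower (blue), FLT3 lies close to the line, and a row of genes expressed in the FLT3-ITD library lies at 0 in the other.

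The 15 protein-coding genes furthest above had 0 to 687 counts in FLT3-ITD cells. XAGE1A and XAGE1B, near-identical copies of a cancer-testis antigen gene on X whose reads cannot be separated, had 2 counts each in FLT3-ITD cells and 1067 and 1050 in FLT3-ITD/D835 cells (514-fold and 505-fold, log2 intervals 7.15 to 12.05 and 7.12 to 12.03). MAGEA4, also known as a cancer-testis antigen gene, had no counts and 238, at least 76.4-fold higher, a lower bound against the limit of 3 counts like all folds against 0 here. S100A8 and S100A9 encode the subunits of calprotectin, an abundant protein of neutrophils and monocytes. S100A8 was at 0 and 6.90 CPM, at least 84.4-fold higher, and S100A9 was at 0.545 and 40.6 CPM (log2 ratio 6.19, 5.59 to 6.94). ELANE (neutrophil elastase; chromosome 19, 850997 to 856250) was at 18.7 and 450 CPM, a log2 ratio of 4.59 (4.48 to 4.70). CSPG4, the NG2 antigen of KMT2A-rearranged leukaemia (chromosome 15, 75674322 to 75712848), was at 4.77 and 135 CPM (log2 ratio 4.82, 4.60 to 5.05). CXCL8, a neutrophil chemokine, had 4 and 254 counts, and CDA, the cytidine deaminase that inactivates cytarabine, had 4 and 288. IL7R, the interleukin 7 receptor, had 2 and 463 counts (223-fold, log2 interval 5.94 to 10.85), and VIT had 2 and 201 (96.8-fold, 4.72 to 9.65). TNN, which encodes the matrix protein tenascin N, and CLSTN2 had no counts in FLT3-ITD cells and were at least 125-fold and 115-fold higher. GPR183, an oxysterol receptor, and DIPK1C completed the group, with log2 ratios of 5.22 (4.61 to 5.97) and 5.38 (4.78 to 6.14).

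The 15 furthest below were expressed at 9.24 to 55.6 CPM in FLT3-ITD cells and had between 0 and 3 counts with D835. ACOT2, a mitochondrial acyl-CoA thioesterase (chromosome 14, 73567620 to 73575658), had 1006 counts and 0, at least 348-fold lower. Its paralog ACOT1 had 184 and 0 and was looked up because the paralogs are similar in sequence. PRDM16, a transcription factor of haematopoietic stem cells, had 682 counts and 0, at least 236-fold lower. PGM1 (phosphoglucomutase), KIF16B (a kinesin), ZFP3, NT5C3B, GLB1L2, RNF157, ZNF717 and PNPLA4 also had no counts with D835. They were at least 186-fold, 181-fold, 181-fold, 179-fold, 171-fold, 150-fold, 147-fold and 117-fold lower, respectively. CREB5 (chromosome 7, 28299321 to 28825894) had 1817 and 2 counts (944-fold lower, log2 interval -12.93 to -8.03) and the potassium channel subunit gene KCNG1 had 2041 and 3 (707-fold lower, -11.74 to -7.92). FZD6, a Wnt receptor, had 785 and 2 counts (408-fold lower, -11.72 to -6.81). The imprinted gene NDN had 752 and 2 (391-fold lower, -11.66 to -6.75), and KRT18, a keratin, had 725 and 2 (377-fold lower, -11.61 to -6.70).

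The gene lists asked which pathways and lineage programmes differed as groups. Of 36 lists with enough measured genes, 14 stood above and 8 below random lists matched on expression. If genes and lists were independent, 1.8 would be expected. Genes of a pathway vary together and some lists share members, so that number is not a limit for chance here. Reference genes also stood above (median 0.26, 98.5th percentile, 20 of 27 with a ratio above 1), while ribosomal protein genes lay below (median -0.17, 0.465th percentile, 49 of 51 with a ratio at or below 1), though not below length-matched lists (2.57th percentile). RPL3 and RPS2 had log2 ratios of -0.24 (-0.25 to -0.23) and -0.04 (-0.05 to -0.03). With length and GC trends removed they were at -0.11 and 0.13, so the direction of RPS2 depends on those trends.

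**Figure D2:**
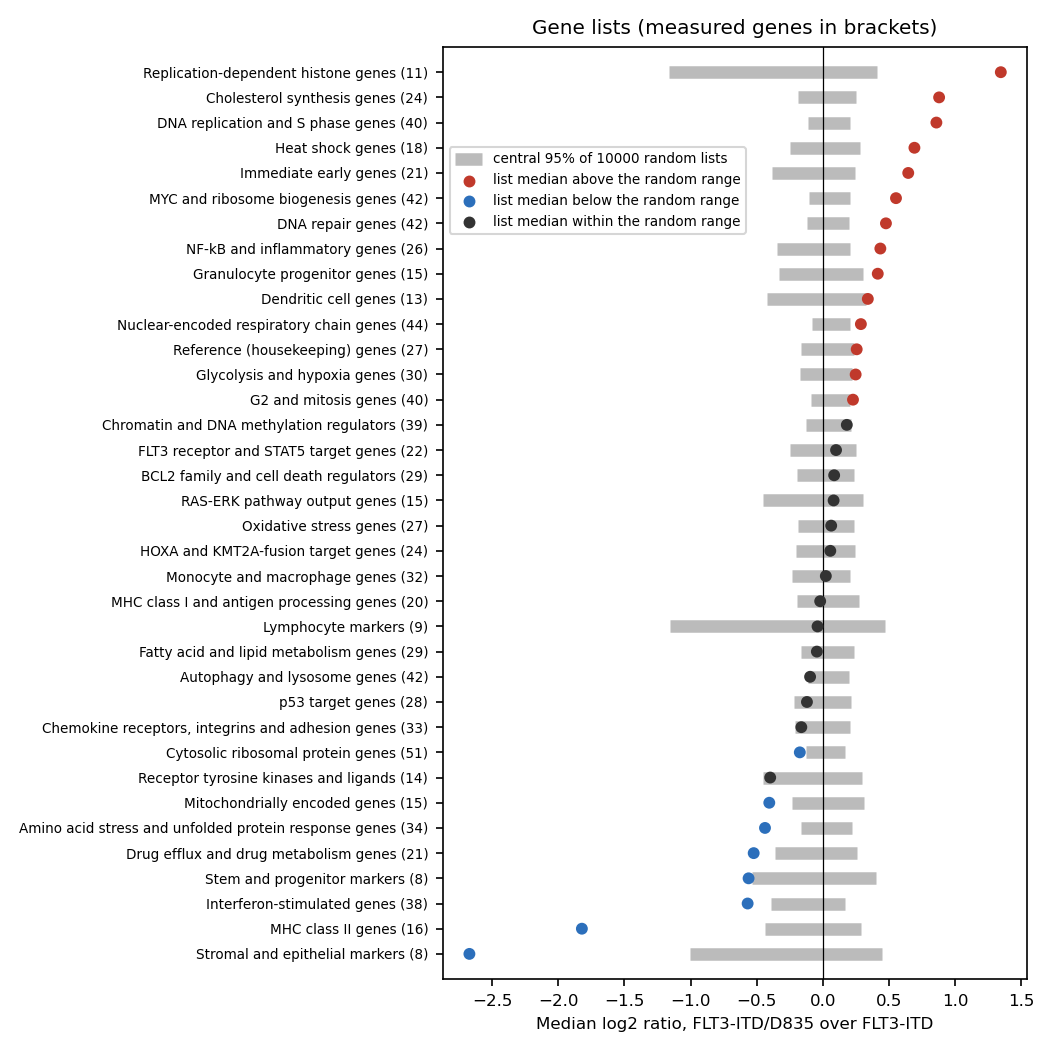
Median log2 ratio (x axis, FLT3-ITD/D835 over FLT3-ITD) of each gene list (points; number of measured genes in brackets) beside the central 95% of 10000 random lists matched on expression (grey bars). DNA replication, cholesterol synthesis and MYC and ribosome biogenesis genes lie to the right of their bars, and MHC class II, interferon-stimulated and amino acid stress genes to the left.

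Genes of DNA replication and biosynthesis were higher with D835 as groups. Of 40 DNA replication and S phase genes 39 had a ratio above 1, 8 were beyond 2-fold and none was lower beyond 2-fold, with a median log2 ratio of 0.86 (100th percentile). MCM4, part of the replicative helicase, was at 254 and 642 CPM (log2 ratio 1.34, 1.31 to 1.37). CLSPN, GINS2 and UHRF1 had log2 ratios of 1.70 (1.57 to 1.83), 1.25 (1.14 to 1.37) and 1.11 (1.07 to 1.15). G2 and mitosis genes had a smaller median of 0.23 (98.8th percentile, with 1 of 40 higher and 1 lower). The reference genes had a median of 0.26, so the mitosis list was raised no more than they were. CKS2 was higher at 1.12 (1.01 to 1.24), a call that ended with length and GC trends removed (1.03, 0.92 to 1.15), and CDC25B lower at -1.33 (-1.43 to -1.22). MYC and ribosome biogenesis genes had a median of 0.55 (100th percentile), with 40 of 42 ratios above 1 and 4 genes beyond 2-fold. NCL (nucleolin) was at 627 and 1338 CPM, a log2 ratio of 1.09 (1.07 to 1.12), and PUS7, UTP20 and HSPE1 had 1.41 (1.29 to 1.53), 1.29 (1.18 to 1.39) and 1.63 (1.38 to 1.89). DNA repair genes had a median of 0.48 (100th percentile; 1 of 42 higher, none lower), led by the uracil glycosylase gene UNG at 1.27 (1.19 to 1.35). Replication-dependent histone genes had a median of 1.35 (100th percentile). Only 11 of 29 listed genes were measured, with 5 higher and 4 at or below a ratio of 1. Whether their values follow DNA replication was not tested. HIST1H1C, HIST1H2BK and HIST1H2AC had log2 ratios of 3.51 (3.28 to 3.76), 2.13 (1.92 to 2.34) and 1.66 (1.28 to 2.07). Histone genes are a multigene family with shared sequence, so their individual values are uncertain. With a filter of 5 CPM too few histone genes were left for a percentile, and by the mean the mitosis list did not stand apart (96.8th percentile).

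Sterol and energy metabolism differed as well. Of 24 cholesterol synthesis genes 7 were higher and 1 lower beyond 2-fold, with a median of 0.88 (100th percentile). HMGCS1, an early enzyme of the pathway, was at 46.3 and 175 CPM (log2 ratio 1.92), INSIG1 at 129 and 409 CPM (1.67, 1.62 to 1.71), and STARD4, a sterol carrier, was 2.79-fold higher. DHCR7, which catalyses the last step of cholesterol synthesis, went against the group at 30.8 and 0.630 CPM (-5.58, -6.26 to -5.03). Fatty acid and lipid genes did not stand apart (median -0.04, 21.8th percentile; 3 of 29 higher, 2 lower). Within them FASN (fatty acid synthase) and SCD (stearoyl-CoA desaturase) were higher, at 1.28 (1.26 to 1.30) and 1.17 (1.14 to 1.20). CD36, a fatty acid receptor, and PLIN2, a lipid droplet protein, were lower, at -2.44 (-2.63 to -2.26) and -1.60 (-1.81 to -1.39). Glycolysis and hypoxia genes had a median of 0.25 (98.7th percentile), no higher than the 0.26 of the reference genes, with 2 of 30 higher and 2 lower. The list did not stand apart by the mean (74.5th percentile) or without the CPM filter (94.6th). PKM and SLC2A3 were higher (1.18, 1.15 to 1.21, and 1.13, 1.03 to 1.23), the call of SLC2A3 ending with those trends removed (1.08, 0.98 to 1.18). The hypoxia-inducible genes VEGFA, at 301 and 90.7 CPM, and DDIT4 were lower (-1.73, -1.79 to -1.67, and -1.80, -1.90 to -1.71). Nuclear-encoded respiratory chain genes had a median of 0.29 (99.9th percentile), close to the 0.26 of the reference genes. Among them 39 of 44 ratios were above 1, and 2 genes were higher. UQCRQ was at 1.20 (1.07 to 1.34). ATP5MC1 was at 1.13 (1.03 to 1.23), and its interval reached inside 2-fold with upper-quartile factors (1.08, 0.98 to 1.19). The 15 mitochondrially encoded genes were all at or below a ratio of 1 (median -0.40, 0.07th percentile). The ribosomal RNAs RNR1 and RNR2 were lower beyond 2-fold, at -1.38 (-1.41 to -1.35) and -1.03 (-1.04 to -1.02). With length and GC trends removed RNR2 lay inside 2-fold, at -0.96 (-0.97 to -0.95). Mitochondrial genes took 7.21% (7.20% to 7.22%, Wilson interval) of the FLT3-ITD counts and 5.41% (5.40% to 5.42%) of the FLT3-ITD/D835 counts.

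Stress genes split by type. Amino acid stress and unfolded protein response genes were lower as a group, with 31 of 34 ratios at or below 1, 5 genes lower and 1 higher beyond 2-fold, and a median of -0.44 (0th percentile). TRIB3, a target of the stress factor ATF4, was at 298 and 44.5 CPM (-2.74, -2.82 to -2.67). PHGDH, the first enzyme of serine synthesis, was at 358 and 81.8 CPM (-2.13, -2.19 to -2.07) and ASNS (asparagine synthetase) at 273 and 125 CPM (-1.13, -1.18 to -1.08). Heat shock genes were higher (median 0.69, 100th percentile; 4 of 18 higher, 1 lower), with HSPH1 at 1.28 (1.22 to 1.34), CHORDC1 at 1.14 (1.02 to 1.26) but inside 2-fold with the trends removed (0.92, 0.80 to 1.03), and HSPA1A lower at -1.59 (-1.90 to -1.30). Oxidative stress genes did not stand apart (median 0.06, 66.2nd percentile; 5 of 27 higher). The metallothionein genes MT1G and MT2A, of a family that shares sequence, were higher at 1.94 (1.84 to 2.05) and 1.44 (1.36 to 1.54). The p53 targets (median -0.12, 12.2nd percentile; 4 of 28 lower) included EDA2R at -6.50 (-8.07 to -5.48), TP53INP1 at -1.62 (-1.89 to -1.36) and SESN2 at -1.14 (-1.23 to -1.05), whose call ended with the trends removed (-1.05, -1.14 to -0.96). Autophagy and lysosome genes had a median of -0.10 (4.18th percentile; 1 of 42 lower), the lower gene being PSAP (prosaposin) at -1.29 (-1.34 to -1.24). No measured gene of the fixed BCL2 family and cell death list was beyond 2-fold (29 genes, median 0.09, 71.0th percentile), and BCL2 and MCL1 had log2 ratios of 0.57 (0.53 to 0.62) and 0.48 (0.43 to 0.52). BCL2L10, a family member outside that list and chosen after its values were seen, had 395 and 2 counts (205-fold lower, log2 interval -10.73 to -5.82).

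Transcripts of MHC class II genes and of interferon-stimulated genes were lower with D835 as groups. Of 16 class II genes 9 were lower beyond 2-fold and none higher, with a median of -1.82 (0th percentile). HLA-DRA was at 61.2 and 1.42 CPM (-5.42, -5.85 to -5.05), HLA-DPA1 at 15.6 and 0.262 CPM (-5.82, -6.96 to -5.00), and HLA-DRB1 at 21.8 and 0.603 CPM (-5.14, -5.84 to -4.58). HLA-DRB5 had a log2 ratio of -5.31 (-6.88 to -4.28), though it shares reads with HLA-DRB1. CIITA, the transactivator of class II genes, is a member of the list outside the rule for named genes. It was chosen after the other class II values were seen, and was at 30.9 and 1.78 CPM (-4.10, -4.49 to -3.76). MHC class I and antigen processing genes did not stand apart (20 genes, median -0.02, 33.9th percentile). Of 38 interferon-stimulated genes 15 were lower and 2 higher (median -0.57, 0.22nd percentile). OAS2, IFI6, RSAD2 and SAMD9L had log2 ratios of -2.31 (-2.62 to -2.02), -1.82 (-2.06 to -1.59), -1.90 (-2.26 to -1.57) and -1.77 (-2.03 to -1.52). NF-kB and inflammatory genes were higher as a group (median 0.44, 99.98th percentile; 8 of 26 higher, 1 lower). TNF was at 6.02 and 42.3 CPM (2.81, 2.61 to 3.02), while the cytokine gene IL18 was at 26.2 and 0.682 CPM (-5.24, -5.88 to -4.70). Immediate early genes had a median of 0.65 (100th percentile; 5 of 21 higher, 1 lower), with EGR3 at 4.59 (3.67 to 5.90), JUN at 2.10 (1.83 to 2.38), RHOB at 1.81 (1.66 to 1.95) and KLF2 at 1.73 (1.52 to 1.95).

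Lineage markers differed in both directions. Granulocyte progenitor genes stood above (median 0.42, 99.6th percentile; 3 of 15 higher, 1 lower), and PRTN3, the azurophil granule protease proteinase 3, was at 216 and 1088 CPM (2.34, 2.30 to 2.37). RNASE3 was at 1.87 (1.56 to 2.21). Monocyte and macrophage genes did not stand apart (median 0.02, 61.3rd percentile), with 5 of 32 higher and 7 lower, although by the mean the list stood above (97.7th percentile). CD68 was at 140 and 33.9 CPM (-2.05, -2.14 to -1.96) and LILRB2 at -2.08 (-2.37 to -1.80), opposite to S100A8 and S100A9. Dendritic cell genes (median 0.34, 97.8th percentile) had 4 of 13 higher and 4 lower, and did not stand apart by the mean (95.9th percentile) or at 5 CPM (94.8th). TCF4 and CLEC10A were higher, at 4.37 (4.11 to 4.66) and 2.25 (2.10 to 2.41), CD83 was at 5.94 and 23.8 CPM, and BATF3 was lower at -2.45 (-2.97 to -1.99). Stem and progenitor markers lay below (8 genes, 3 lower, median -0.56, 2.03rd percentile) but not without the CPM filter (45.9th percentile) or against length-matched lists (3.09th), and at 5 CPM too few were left. KIT was at 27.1 and 10.8 CPM (-1.32, -1.49 to -1.16). HOXA and KMT2A-fusion target genes did not stand apart (median 0.06, 61.4th percentile; 3 of 24 higher, 1 lower). The posterior genes HOXA11, at 2.75 and 46.4 CPM (4.07, 3.79 to 4.38), and HOXA13 (2.32, 1.82 to 2.88) were higher, as was ELL2 (1.30, 1.04 to 1.57), and MEF2C was lower at -1.42 (-1.74 to -1.12). The calls of ELL2 and MEF2C ended on halved counts, where the intervals were 0.93 to 1.69 and -1.90 to -0.997. Chromatin and DNA methylation regulators had no gene beyond 2-fold (39 genes, median 0.18, 94.9th percentile), with DNMT1, the maintenance methyltransferase, at 0.48 (0.45 to 0.51).

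Most markers of other cell types were not measured above the filter. Lymphocyte markers did not stand apart (9 measured of 33, median -0.04, 71.9th percentile; 3 higher, 3 lower), with IGLL1 at 3.10 (2.62 to 3.65) and BANK1 at -2.87 (-3.42 to -2.40). Stromal and epithelial markers lay below (8 measured of 22, 4 lower, median -2.67, 0.01st percentile), and at 5 CPM too few were left for a percentile. KRT8 was at 14.2 and 0.787 CPM (-4.15, -4.76 to -3.64) and COL6A1 at 26.6 and 1.94 CPM (-3.77, -4.14 to -3.43). Only 6 of 28 erythroid and megakaryocyte markers were measured, too few for a percentile. TFRC, the transferrin receptor, was higher at 1.33 (1.30 to 1.37) and ITGA2B lower at -1.32 (-1.52 to -1.13).

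Receptors and drug-handling genes were compared because D835 substitutions are known for resistance to some FLT3 inhibitors. Receptor tyrosine kinases and ligands did not stand apart (14 measured, median -0.40, 4.27th percentile; 2 higher, 4 lower). FGFR3 was lower at -3.60 (-4.09 to -3.17), FLT3LG, the FLT3 ligand, at -1.53 (-1.92 to -1.16) or, with the trends removed and no longer called, -1.35 (-1.74 to -0.99), and PDGFA was higher at 2.90 (2.71 to 3.11). Drug efflux and metabolism genes lay below (21 measured, 2 higher, 5 lower, median -0.52, 0.25th percentile), but not by the mean (9.68th percentile) or at 5 CPM (30.5th). CYP1B1, a xenobiotic-metabolising cytochrome, was at 26.3 and 0.682 CPM (-5.24, -5.89 to -4.71), GSTM2 at -2.06 (-2.42 to -1.73) and the carrier gene SLC22A4 at 1.77 (1.46 to 2.10). Chemokine receptors, integrins and adhesion genes did not stand apart (33 measured, median -0.16, 6.38th percentile; 3 higher, 6 lower). ITGAV was higher at 2.46 (2.18 to 2.75), CLEC12A, a myeloid leukaemia surface antigen, at 2.58 (2.14 to 3.08), and ITGAM (-1.93, -2.24 to -1.64) and CD38 (-1.80, -2.11 to -1.51) were lower.

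Differences were uneven along the genome. Of 23 chromosomes (the autosomes and X), 5 stood above and 5 below random gene lists, where 1.15 would be expected if genes varied independently. Chromosomes were not repeated with length and GC trends removed, so the part of such trends in their medians is not known. The lowest medians were those of chromosome 20 (-0.20, 323 genes), chromosome 19 (-0.13, 940 genes) and chromosome 10 (-0.11, 450 genes), and the highest was that of chromosome 5 (0.16, 513 genes). When the arms were separated, a step chosen after the chromosome values were seen, the shift on chromosomes 10 and 20 lay on their short arms. On the short arm of chromosome 20 the median was -0.95, 93 of 101 protein-coding genes had a ratio below 1, and 38 were lower and 1 higher beyond 2-fold, while the long arm had a median of -0.01 (222 genes). On the short arm of chromosome 10 the median was -0.86, with 93 of 99 ratios below 1 and 32 genes lower, against 0.05 on its long arm (351 genes). The other 39 arms had medians between -0.17 and 0.21. These short arms held 77 of the 1016 lower genes, among them TRIB3, CDC25B and KIF16B on chromosome 20.

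**Figure D3:**
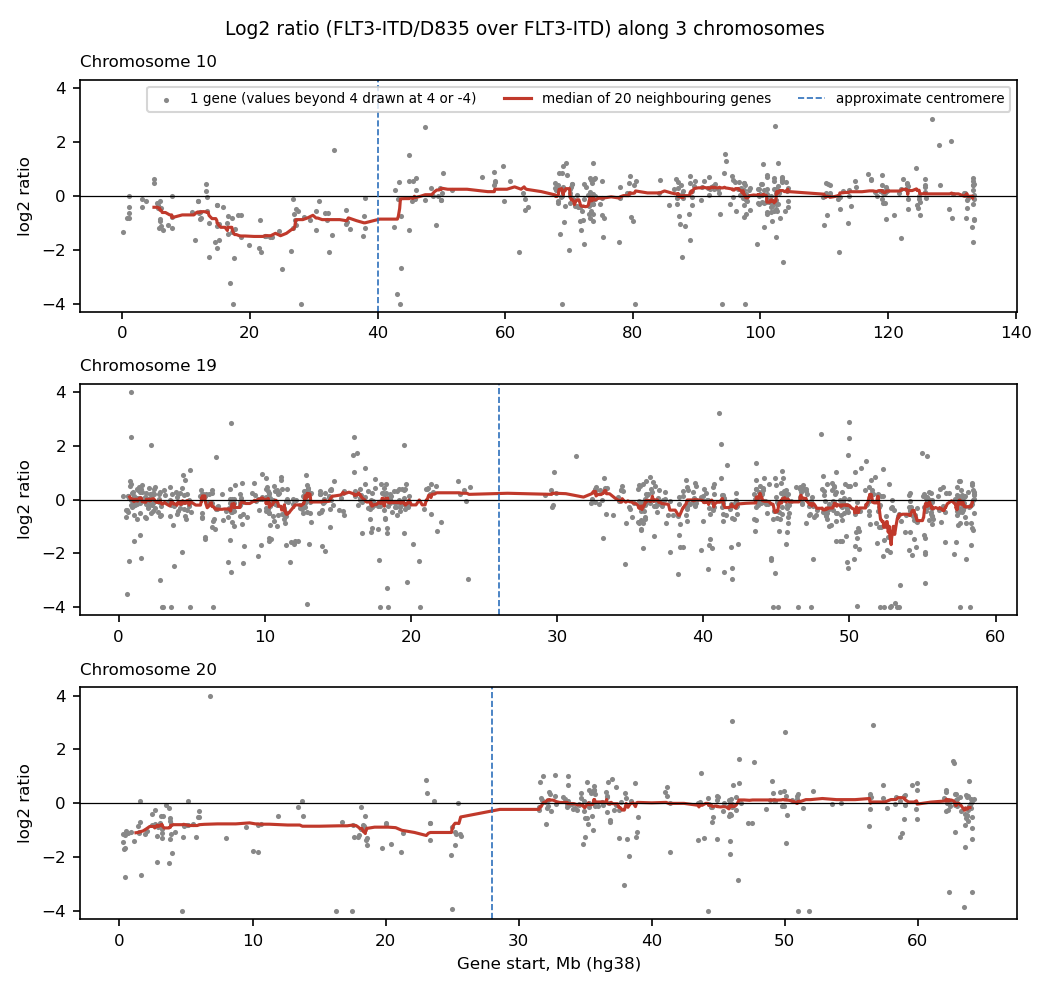
Log2 ratio (y axis, FLT3-ITD/D835 over FLT3-ITD) of each expressed protein-coding gene by its start (x axis, Mb, hg38) on chromosomes 10, 19 and 20, with the running median of 20 neighbouring genes (red) and the approximate centromere (dashed). The running median stays below 0 along the short arms of chromosomes 10 and 20 (arm medians -0.86 and -0.95) and returns to about 0 on their long arms.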

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

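The tests on halved counts, without mitochondrial genes and without the short arms of chromosomes 10 and 20 were chosen after the data were seen. With 1 library per genotype no replicate could be left out, and the spread between replicates was not measured. Depth limits the calls as well, since halved counts gave 372 higher and 887 lower genes. No paired analysis was possible because each group holds 1 library. The number of genes higher (459) and lower (1016) with D835 moved by over 1.5 times only with other thresholds or filters. An interval beyond 1.5-fold gave 1115 higher and 1809 lower genes, and beyond 4-fold 140 and 391. The point estimate alone gave 697 higher genes (1431 lower), and a filter of 5 CPM left 644 lower genes (329 higher), since fewer genes were tested. Under the other scalings, without the filter, with 5 added counts, without length and GC trends, among protein-coding genes, after thinning, and in the tests named first, higher genes numbered 372 to 591 and lower genes 887 to 1318. The log2 ratio of FLT3 left its counting interval with upper-quartile factors (-0.26), which shift every ratio by -0.05. The number of lists apart was 17 to 22 and of chromosomes 9 or 10. Neither number was repeated with length and GC trends removed, though lists were also compared with length-matched random lists. Of the 22 lists apart, 14 kept their side under length matching, both other filters, means and another random seed, where a list with too few genes left counts as not kept. RPS2, which was not called, changed sign with trends removed. No called direction among the 127 other named genes reversed under the other scalings, added counts or trend removal. Outside their counting interval lay 17 of them with upper-quartile factors, 14 with 5 added counts, 27 with trends removed and 1 each with DESeq2 and total-count scaling. Of 120 called named genes, calls ended for 7 with trends removed (CHORDC1, CKS2, ELL2, FLT3LG, RNR2, SESN2 and SLC2A3), for 5 with upper-quartile factors (ATP5MC1, CHORDC1, CKS2, ELL2 and SLC2A3) and for 6 on halved counts (those 5 and MEF2C). None ended with DESeq2 or total-count scaling, 5 added counts or thinning.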

Other observations

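The tests of depth, of HLA alleles and of a whole-chromosome loss were chosen after the results they bear on were seen, as were the chromosome arms, and CIITA was chosen after the other class II values were seen. For the whole-chromosome test the excluding criterion was also restated after the arm values were seen, from both arms being near 0 to at least 1 arm being so. The interval of the CpG-rich share was also added after that share was seen.

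Zinc finger genes on chromosome 19 (symbols beginning ZNF, ZFP or ZSCAN) were lower with D835 as a group. Of 209 expressed genes 34 were lower and none higher beyond 2-fold (median log2 ratio -0.19, 0.25th percentile), while the 239 on other chromosomes had 24 lower and 7 higher (median -0.02, 50.9th percentile). The lowest stretch of 20 neighbouring genes on chromosome 19, from 52331863 to 53458261, held 20 zinc finger genes, 12 of them lower, with a median of -1.67. The hypothesis that these genes account for the low median of chromosome 19 failed its test. Without them the chromosome stayed at percentile 0.0 of random lists (731 genes, 74 lower and 19 higher, median -0.12). Length and GC trends were not removed for this test, so their part in that median is not known.

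Transcripts found in the FLT3-ITD library and nearly absent from the other were more frequent than the reverse. On 22 chromosomes, 69 protein-coding genes had at least 100 counts in FLT3-ITD and at most 3 with D835, PRDM16, PGM1 and NDN among them, and 13 genes showed the reverse. Lower depth is argued against by the totals, whose ratio was 1.03. Loss of segments that reach the nearest expressed neighbours is argued against for these genes as a set, since the neighbours' median log2 ratio was -0.016. However, 29 of 137 neighbours were below -1, a larger share than the 1431 of 12843 expressed genes with a point estimate at or below that value. The neighbours came from a narrower set of genes, so these shares are not strictly alike. For 4 genes the neighbours on both sides were below -1. A median cannot show losses at a minority of loci, so single loci may differ. The neighbours lay a median of 144 kb away, so smaller losses confined to a gene were not tested. Silencing at CpG-rich promoters would give an excess of CpG-rich transcript starts among these genes, and no such excess was found. Their share was 63.8% (exact 95% interval 51.3% to 75.0%), against 64.2% of all genes in the pool for random draws. It lay at the 87.3rd percentile of random genes, inside their central range of 44.9% to 68.1%. This result gives no support to such silencing. It does not exclude it, because the interval reaches above that range. Differences between clones or cultures and the D835 genotype stay open and untested.

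Lower CIITA as an origin of the lower class II counts stays open. Its log2 ratio was -4.10 (-4.49 to -3.76), but CIITA is a member of the class II list, so its low value is part of the pattern and adds no separate support. Alleles that differ from the reference would spare the less polymorphic genes, but HLA-DRA, HLA-DMA, HLA-DMB and CD74 had a median of -2.23. HLA-DRA was at -5.42. HLA-DMA (-2.49), CD74 (-1.97) and HLA-DMB (-1.67, -2.74 to -0.78) were lowered less than the polymorphic HLA-DRB1 (-5.14). These values argue against alleles as the only origin, and a partial effect on the polymorphic genes stays open. Whether lower CIITA precedes the other differences was not tested, and cells of another type, clone or culture differences and the genotype stay open.

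A copy fewer of a segment of chromosome 20 in the D835 cells is a candidate explanation for the low median of that chromosome. The lowest 20 neighbouring genes there, from 18507544 to 25298012, had a median of -1.20, below the -0.86 that bounds the lowest 5% of 1000 random gene orders. The lowest stretch of chromosome 19 (-1.67, all zinc finger genes) passed the same bound, so passing it does not by itself point to a lost copy. That of chromosome 10 (-1.51) passed it too. It lies on a short arm with a median like that of the short arm of chromosome 20 (-0.86 and -0.95), so it does not bear on this point. Loss of the whole chromosome is argued against by its median of -0.20, because a long arm at -0.01 leaves no room for it. Silencing across the region, the genotype and the descent of the cells stay open, and DNA copy number is not analysed here.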
